A study of Danio rerio with 8 samples.

How the data were processed

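Gene expression was measured by RNA sequencing in zebrafish (Danio rerio) of the TU strain. The labels give 6 libraries from hearts at 21 days post fertilisation (dpf), 3 of control and 3 of zfpm1 mutant fish, and 2 libraries from embryos at 36 hours post fertilisation (hpf), 1 of each genotype. Per the labels' protocols, tissue was flash frozen, RNA was extracted with Trizol, and libraries were made from 1 ug of total RNA with an Illumina TruSeq RNA kit, using oligo(dT) beads, fragmentation and random hexamers. That protocol includes no step that marks the strand of the RNA. The labels do not say whether the libraries of a group came from separate animals or pools, so p-values measure only the spread between these libraries, which may be partly technical.

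The deposited values are raw read counts per gene, 1 file per library, which the authors made before any normalisation. Per the submitters' processing notes, the tools were bcl2fastq, FastQC 0.11.5, TopHat2 2.2.1, Bowtie2 2.2.3 and HTSeq 0.6.1p1, with the genome build GRCz10. The strand setting of the counting and the annotation release are not given in the sources used here. Each file lists 31953 gene IDs and the counter's lines for reads not assigned to a gene. In the heart files 42.4% to 48.8% of all lines' total was in no annotated feature, 11.1% to 21.8% was not uniquely aligned and 0.601% to 1.08% was ambiguous. In the files labelled as embryo 10.0% and 9.53% was in no feature. These lines were left out of library sizes and tests. Total gene counts ranged from 7614329 to 9909966 in the heart files, and were 14689165 and 16756796 in the files labelled control and mutant embryo.

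Gene symbols came from a table of gene IDs, which named 26121 of the 31953 IDs. Of these, 11871 carry a human-style capital symbol, and 1630 symbols are carried by more than 1 ID, so a symbol can stand for several zebrafish paralogs. Coordinates were not used here, since no genome of the build was at hand. Counts of near-identical paralogs, the globin genes above all, are uncertain, since the authors' counting could split or drop their reads.

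The 6 heart libraries were compared with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with a minimum count of 10, library sizes were scaled by TMM, and the quasi-likelihood F test compared mutant with control with group as the only term. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. All adjusted p-values below are from this test unless another is named. Expression is given as TMM-scaled CPM, counts scaled to a common library size, as mean ± SD, and fold changes as log2 of mutant over control with their standard error (SE). A gene with 0 counts in all libraries of a group was set to a floor of 3 counts over that group, 0.124 CPM in control and 0.106 CPM in mutant hearts, and its fold is a lower bound. Floors and exact intervals of counts cover counting error only, while the interval of a fitted fold change also covers the spread between libraries.

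Gene lists, 39 in all, were fixed before the data were examined, as were the design, the settings to be compared and the rule for naming genes. Lists with at least 5 tested members were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, then with an estimated correlation, and with fry. Counts of called members are also given with p-values adjusted over the list alone. Beta-globin names were matched to the table's symbol HBE1 after the symbols had been seen.

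The rule named zfpm1 and its paralogs; the 12 higher and 12 lower called genes with the largest absolute log2 fold change, a mean of at least 2 CPM, groups that do not overlap and a symbol that is not provisional; and up to 4 called members per list with the smallest adjusted p, with the 2 most abundant members where fewer than 4 were called. For the embryo labels it named the 10 higher and 10 lower genes past the size rule. Members of this set that are described further on are examples from it, and some genes it takes are not reported here.

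With 1 library per genotype the embryo labels allow no test. There the planned description was the log2 ratio of TMM-scaled CPM with a prior count of 2, a size rule of at least 2-fold with at least 100 counts in either library, and the percentile of a list's median among 10000 random lists matched on mean expression, over members with at least 20 counts in both libraries together. After the files had been examined, each file labelled as embryo was set against each heart file, over genes with at least 50 counts in the embryo-labelled file.

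The steps were tested on simulated counts for 16913 genes that passed the filter, drawn from the means, library sizes and dispersions of the heart libraries. Of 100 genes shifted 2-fold 14% were recovered, and of 100 genes shifted 4-fold 84% were recovered. A list of 60 further genes was shifted 2-fold as a whole, and 20 of its genes were called. Among 120 calls in all 2 were false, and the only list called of 38 was the shifted one. The genes shifted singly had a mean above 2 CPM. All genes were drawn independently of each other, so the simulation cannot show how often lists are falsely called when their genes vary together.

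The hearts were also compared with RLE size factors, library size alone, DESeq2 1.42.0, limma-voom, no low-count filter, a filter of 1 CPM in at least 3 libraries, a replicate block, each library left out in turn, haemoglobin and mitochondrial genes left out, and a 2-fold minimum. For the embryo labels the scaling, prior count, count minimum and fold minimum were changed. Further settings were chosen after seeing the data: leaving out both heart libraries numbered 1, and leaving out 708 genes whose heart count was under 0.35 or above 0.65 of the count in the matching embryo-labelled file. Library size alone moved the median log2 fold change of all tested genes by 0.26 relative to TMM, so small shared shifts depend on the scaling.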

Results

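Transcripts were counted in 21 dpf hearts and, per the labels, in 36 hpf embryos of control and zfpm1 mutant zebrafish, to find genes downstream of zfpm1 in embryogenesis and in the maturation of the heart chambers. zfpm1 encodes a FOG family zinc finger cofactor of GATA transcription factors. Control hearts gave 8741419, 9632464 and 8197337 gene counts in replicates 1 to 3, and mutant hearts gave 7614329, 8482698 and 9909966. The library labelled control embryo gave 14689165 and the library labelled mutant embryo 16756796. The first principal component of the heart libraries held 61.5% of the variance and separated the genotypes.

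The files labelled as embryo matched 2 of the heart libraries. The total of all lines was 19276348 both in the library labelled control embryo and in mutant heart replicate 1, with 2130930 reads not uniquely aligned in each. The total was 22649056 both in the library labelled mutant embryo and in control heart replicate 1, with 2907502 not uniquely aligned in each. In these pairs a gene's heart count was at or below its embryo-labelled count in 98.8% of 14361 and 98.8% of 12894 genes. The median ratio was 0.503 and 0.504. In the other pairs the share was 87.8% to 97.0% and the ratio 0.433 to 0.619. The ratio alone therefore does not set the matched pairs apart. The cardiac myosin light chain gene MYL7 stood at 6311 CPM in the library labelled control embryo and 12466 CPM in that labelled mutant embryo, and the neuronal gene ELAVL3 at 5.24 and 0.298 CPM (CPM of gene counts without TMM). The heart libraries had MYL7 at 6102 to 12002 CPM. Both ends of that range are the matched libraries, and the other hearts had 8180 to 10456 CPM. ELAVL3 stood at 5.91 CPM in mutant heart replicate 1 and at 0.458 to 1.59 CPM in the other hearts. Across genes, which are not independent replicates, control heart replicate 1 had a Pearson r of log2 CPM of 0.926 and 0.953 with the other control hearts and of 0.813 to 0.876 with mutant hearts, and mutant heart replicate 1 had an r of 0.927 and 0.930 with the other mutant hearts and of 0.808 to 0.817 with control hearts. The paired labels differ in tissue and in genotype, and the embryo-labelled files were not used as independent samples.

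The zfpm1 transcript (ZFPM1, ENSDARG00000041572) was present in mutant hearts and its level did not pass the test. Counts were 419, 344 and 423 in control hearts and 558, 471 and 956 in mutant hearts. Its level was 49.0 ± 5.80 CPM in control and 69.2 ± 20.4 CPM in mutant hearts (SD, n = 3 each), a log2 fold change of 0.50 with an SE of 0.23 and an edgeR adjusted p of 0.241. The 95% interval ran from -0.03 to 1.03. A mutant allele need not lower its transcript, so these counts neither contradict nor check the genotype labels. The library labelled control embryo held 1147 zfpm1 counts and the library labelled mutant embryo 858. The paralogs did not pass either: ZFPM2 had a log2 fold change of 0.21 (SE 0.22, adjusted p 0.628) and zfpm2b of 0.33 (SE 0.30, adjusted p 0.572).

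**Figure D1:**
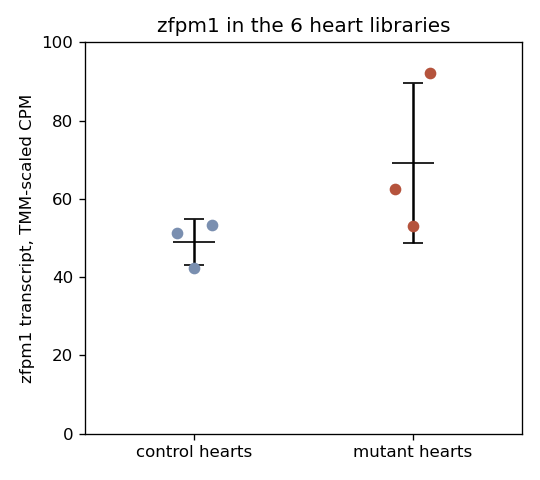
zfpm1 transcript in TMM-scaled CPM (vertical axis) in 3 control and 3 mutant hearts; points are libraries, the horizontal mark is the mean and the bars are ± SD. Means were 49.0 CPM in control and 69.2 CPM in mutant hearts, and the groups overlap.

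Mutant hearts differed widely from control hearts, with globin and other red cell transcripts far lower and transcripts of liver and myeloid cells higher. Of 16707 genes tested, 1576 were called, 1172 higher and 404 lower in mutants, and 3948 had an unadjusted p under 0.05. The groups did not overlap in 1575 of the called genes and in 29.7% of all tested genes, where chance gives 10% for 3 libraries against 3. With library size alone as scaling, 87.5% of calls were higher, against 74.4% with TMM. Without both libraries numbered 1, which match the embryo-labelled files, 1255 genes were called, 876 higher and 379 lower, of which 1029 were among the 1576. The count fell to 1034 without control replicate 2 and to 604 without control replicate 3. Leaving out 1 library lost from 436 (mutant replicate 3) to 978 (control replicate 3) of the 1576 calls. A call lost in this way need not mean that the gene's change rests on that library.

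The 12 genes with the largest rise included 9 without a count in any control heart. Among these were the gap junction gene gja13.1 (ENSDARG00000041787), at 26.8 ± 25.7 CPM in mutants and at least 216-fold higher, and hamp (ENSDARG00000102175), which encodes the liver iron hormone hepcidin, at 13.8 ± 10.5 CPM and at least 111-fold higher. The hedgehog ligand gene ihha (ENSDARG00000058733) was at least 106-fold higher. TM4SF4 was at least 99.4-fold higher, and HNF4A, a transcription factor of liver and gut epithelium, was at least 63.2-fold higher. The zinc transporter gene slc39a4, gpa33b and MNX1 were at least 62.7-fold, 61.7-fold and 61.0-fold higher. The 3 with counts in controls were stm, known for its role in otoliths, at a log2 fold change of 9.54 (SE 1.33), the gluconeogenic enzyme gene FBP2 at 9.24 (SE 0.79), and the metal transporter gene SLC39A8 at 9.21 (SE 1.34). SLC39A8 had 2 counts over all control hearts, both in replicate 1, and 1561 in mutant hearts, a ratio of 670 with an exact 95% counting interval of 185 to 5538. Its log2 fold change was 7.52 and that of stm 7.57 without mutant replicate 1, which held 137 CPM of SLC39A8 and 643 CPM of stm against 16.7 and 65.5 CPM in mutant replicate 2. Many of these were most abundant in mutant replicate 1, as in HNF4A with 15.8, 6.08 and 1.64 CPM and MNX1 with 18.1, 2.81 and 1.73 CPM in mutant replicates 1 to 3. Without that library the lower bounds were 97.4-fold for gja13.1, 63.8-fold for ihha, 38.5-fold for TM4SF4, 31.2-fold for HNF4A, and 17.3-fold, 17.6-fold and 18.3-fold for slc39a4, gpa33b and MNX1, and FBP2 had a log2 fold change of 8.46; without mutant replicate 2 the bound for hamp was 66.4-fold. In mutant replicate 1 ihha had 211 counts against 176 in the matching embryo-labelled file, and FBP2 had 0.705 of the embryo-labelled count, where the median ratio was 0.503. The calls of slc39a4 and gpa33b were lost without any 1 control, with edgeR adjusted p up to 0.0870 and 0.0905. That of MNX1 was lost without control replicate 2 or 3, with adjusted p up to 0.0824. Those of TM4SF4 and HNF4A were lost without control replicate 3, at adjusted p 0.0529 and 0.0547.

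The 12 genes with the largest fall were 10 globin genes, the nucleotidase gene nt5c2l1 and ifi44f1. The adult-type alpha globin gene hbaa1 (ENSDARG00000097011) fell from 2832 ± 2200 to 6.86 ± 9.36 CPM, a log2 fold change of -8.69 (SE 1.34, adjusted p 0.00517). The genes hbae3, hbae1.3, hbae1.2, hbae5 and hbae4 had log2 fold changes of -8.44, -8.08, -7.54, -7.83 and -7.77. The 4 IDs carrying the symbol HBE1 had log2 fold changes of -9.66 (ENSDARG00000097238), -8.54 (ENSDARG00000089087), -8.49 (ENSDARG00000087390) and -7.91 (ENSDARG00000045143). The counts of hbae5 and of the last of these departed from the usual ratio, at 0.879 and 1.01 of the embryo-labelled count in control replicate 1. Their calls were lost without control replicate 2, control replicate 3 or mutant replicate 2, with edgeR adjusted p up to 0.0805 and 0.0733. Mutant replicate 1 held the most counts of each of these globin genes among the mutant hearts. It held all 22 counts of HBE1 ENSDARG00000097238 and all 6 of hbae4, so the size of their fold changes rests on that library, while their fall does not. With 1 library left out these log2 fold changes reached -15.46 and -11.76, and neither call was lost. The count of hbae4 was 0.240 of the embryo-labelled count in mutant replicate 1. Without mutant replicate 1 the log2 fold changes were -12.38 for both hbae5 and ENSDARG00000045143, -12.26 for ENSDARG00000087390, -10.79 for hbaa1, -10.39 for ENSDARG00000089087, -9.91 for hbae1.3, -9.70 for hbae3 and -9.69 for hbae1.2. nt5c2l1 fell from 178 ± 59.5 to 1.35 ± 1.74 CPM, with a log2 fold change of -7.05, and of -8.87 without mutant replicate 1, which held 3.36 CPM against 0.230 and 0.480 CPM in the others. ifi44f1 had no count in mutants and stood at 17.5, 1.60 and 1.51 CPM in control replicates 1 to 3, so its size depended on control replicate 1. Its call was lost without control replicate 3 or any 1 mutant, with adjusted p up to 0.0686.

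Red cell transcripts fell as a group in mutant hearts. Of 38 tested members of the erythroid list 34 fell and none rose, with a median log2 fold change of -3.46; 34 were lower and 1 higher adjusted over the list alone. The red cell membrane skeleton genes epb41b and ANK1 fell from 288 to 5.89 CPM (log2 -5.61, SE 0.34) and from 113 to 1.998 CPM (log2 -5.80, SE 0.38). klf1, a transcription factor of red cell differentiation, fell by 4.16 on the log2 scale (SE 0.29), with a count of 0.672 of the embryo-labelled count in mutant replicate 1. The biliverdin reductase gene blvrb fell by 3.26 (SE 0.23). The list took 3.46%, 5.26% and 3.51% of gene counts in control hearts and 0.163%, 0.0963% and 0.107% in mutant hearts, replicates 1 to 3. The camera adjusted p was 4.49e-37, the adjusted p = 0.0528 with an estimated correlation, and 0.00139 with fry. Without both libraries numbered 1, 31 of 39 members fell.

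Among other blood lists, thrombocyte genes moved in both directions. Of 14 tested members 3 fell, which encode platelet surface receptor chains, gp9 from 15.1 to 0.887 CPM, GP1BB with a log2 fold change of -2.98 (SE 0.43) and itga2b with -4.55 (SE 0.80) (without mutant replicate 2, -3.61 for GP1BB and -5.80 for itga2b), and 2 rose, among them RASGRP2 with 2.65 (SE 0.37). Adjusted over the list alone, 4 were lower and 6 higher; camera adjusted p was 0.866, and the list's median of 0.26 and mean of -0.24 differ in sign. Of 18 hematopoietic regulators the erythroid and megakaryocyte regulator GFI1B fell by 3.33 (SE 0.53), with -4.03 without mutant replicate 2, and LMO2 by 1.53 (SE 0.22), and the myeloid regulators SPI1, whose count was 0.806 of the embryo-labelled count in control replicate 1, and spi1a rose by 1.73 (SE 0.23) and 1.76 (SE 0.25). In all 4 fell and 2 rose, 4 lower and 5 higher adjusted over the list alone, and the camera adjusted p was 0.652. Without control replicate 2 or 3 only 2 were lower, and without mutant replicate 1 or both libraries numbered 1 5 were higher.

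Myeloid transcripts rose. Of 40 tested members 35 rose and none fell, with a median log2 fold change of 1.97; 38 were higher adjusted over the list alone. The macrophage gene MPEG1 rose from 19.2 to 71.8 CPM (log2 1.90, SE 0.18), the phagocyte oxidase gene cybb from 7.38 to 56.7 CPM (log2 2.94, SE 0.27), and apoc1 and TIMP2 by 2.93 (SE 0.19) and 3.21 (SE 0.27). The camera adjusted p was 5.31e-30, the adjusted p = 0.100 with an estimated correlation, and 0.00479 with fry. Without both libraries numbered 1, 33 of 40 members rose, and without control replicate 3, 21 of 41. Of 34 interferon and inflammation genes 16 rose and none fell, and 26 were higher adjusted over the list alone; without control replicate 3, 10 rose. The leading members were complement genes made in the liver, c3a.2 (log2 5.64, SE 0.40), c3a.1 (5.69, SE 0.67) and cfb (7.67, SE 0.94), with the cytokine gene il11a (3.84, SE 0.47). c3a.1 stood at 832, 204 and 184 CPM and cfb at 226, 49.9 and 36.4 CPM in mutant replicates 1 to 3, and without mutant replicate 1 their log2 fold changes were 4.64 and 6.42. The camera adjusted p was 5.96e-13, and the adjusted p = 0.100 with an estimated correlation. Of 9 lymphoid genes blnk, whose count was 0.684 of the embryo-labelled count in mutant replicate 1, rose by 2.15 (SE 0.39) and CCR9 by 2.27 (SE 0.57). The call of CCR9 was lost without any 1 control or without mutant replicate 2, with adjusted p up to 0.161. Its log2 fold change ran from 1.42 to 2.63 with 1 library left out. The lymphoid camera adjusted p was 0.0384, and the adjusted p = 0.611 with an estimated correlation. That camera call rested on single libraries: without mutant replicate 2 the list's median fell from 2.27 to 0.63 with an adjusted p of 0.299, and the adjusted p was 0.133 without control replicate 1 and 0.0685 with a filter of 1 CPM in at least 3 libraries.

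Liver transcripts showed the largest rise of any list. Of 27 tested members 25 rose and none fell, with a median log2 fold change of 5.46, and 26 were higher adjusted over the list alone. The protease inhibitor gene serpina1l rose from 3.59 ± 0.620 to 292 ± 66.0 CPM (log2 6.34, SE 0.29, adjusted p 4.40e-05). The complement gene c9, whose count was 0.652 of the embryo-labelled count in mutant replicate 1, rose from 1.65 to 150.2 CPM (log2 6.50, SE 0.33), ahsg1 from 0.864 to 54.6 CPM (log2 5.95, SE 0.38) and the apolipoprotein gene apoa2 from 31.0 to 677 CPM (log2 4.45, SE 0.33). The list took 0.0576%, 0.0521% and 0.0516% of gene counts in control hearts and 1.12%, 0.808% and 0.618% in mutant hearts, replicates 1 to 3. The camera adjusted p was 1.21e-30, the adjusted p = 0.100 with an estimated correlation, and 0.00347 with fry. Without both libraries numbered 1, 25 of 27 members rose.

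**Figure D2:**
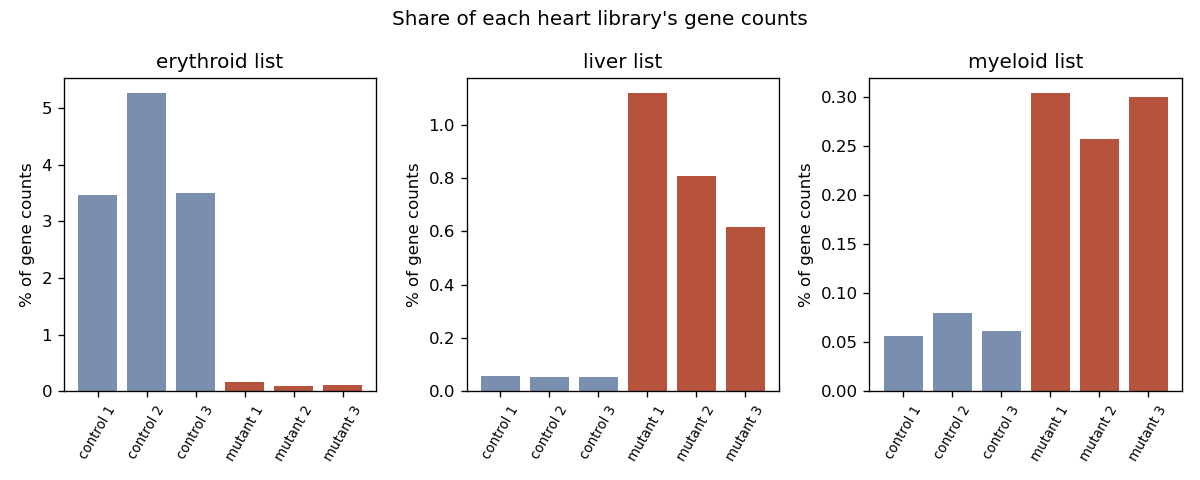
Share of gene counts in percent (vertical axes) taken by the erythroid, liver and myeloid lists in each of the 6 heart libraries (bars). The erythroid share lies between 3.46% and 5.26% in controls and between 0.0963% and 0.163% in mutants, and every liver and myeloid share is higher in mutants than in controls.

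Heart muscle genes lay slightly lower in mutants, and few passed the test. Of 43 sarcomere genes 6 fell and none rose, with a median of -0.66; 8 were lower and 1 higher adjusted over the list alone. NRAP, a myofibril assembly gene, fell from 128 to 31.6 CPM (log2 -2.02, SE 0.21), FLNC fell by 1.63 (SE 0.36), and the thin filament genes carrying the symbol LMOD2 fell by 2.03 (SE 0.43) and 1.34 (SE 0.29). The FLNC call was lost without control replicate 1, control replicate 3 or mutant replicate 2, with adjusted p up to 0.0933. The LMOD2 calls were lost without mutant replicate 1 (both), mutant replicate 3 (ENSDARG00000045864) or control replicates 1 or 3 (ENSDARG00000045634), with adjusted p up to 0.0716. Without both libraries numbered 1 the sarcomere median was -0.25, with 4 lower and 1 higher. Only 2 sarcomere genes were lower without control replicate 3, and 3 without control replicate 1, mutant replicate 1 or mutant replicate 2; DESeq2 called 14 lower and 1 higher. Of 11 genes of the cardiac stress list 4 fell, against 1 without control replicate 3 and 2 without control replicate 1 or mutant replicate 3, and 7 with DESeq2, among them the mechanically induced gene ANKRD1 by 3.10 (SE 0.40) and the xirp1 genes by 3.51 (SE 0.71) and 1.61 (SE 0.37). The natriuretic peptide gene nppal rose by 2.98 (SE 0.76), a call lost when any 1 library other than mutant replicate 3 was left out, with adjusted p up to 0.151 and log2 fold changes from 2.12 (without mutant replicate 1) to 3.64 (without control replicate 2). The xirp1 calls were lost without control replicate 3 or mutant replicate 1 (both), and the second also without control replicate 1 or mutant replicate 3, with adjusted p up to 0.0833. The log2 fold change of the first ran from -4.78 to -3.03 with 1 library left out. Camera adjusted p was 7.09e-07 for sarcomere and 0.000391 for cardiac stress, and the adjusted p = 0.557 and 0.211 with an estimated correlation.

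The chamber lists and cardiac transcription factors gave few calls. None of 5 atrial genes passed with edgeR, DESeq2 or limma-voom, and 0 had an unadjusted edgeR p under 0.05, as for NR2F2 with a log2 fold change of -0.16 (SE 0.16). The list's camera adjusted p was 0.449. Of 4 ventricular genes, too few for a list test, nkx2.7 rose, and MYH7 had a log2 fold change of -0.70 (SE 0.45, adjusted p 0.393) and IRX1 of -0.65 (SE 0.25, adjusted p 0.153). Of 24 cardiac transcription factors nkx2.7 rose by 1.59 (SE 0.35) and HEY1 by 2.98 (SE 0.80), both at under 10 CPM. The nkx2.7 call was lost when any 1 library other than mutant replicate 2 was left out and the HEY1 call when any 1 library was left out, with adjusted p up to 0.106 and 0.136, and the HEY1 value was 4.11 without control replicate 2. The count of nkx2.7 was 0.660 of the embryo-labelled count in mutant replicate 1. DESeq2 called 5 of the cardiac transcription factors and limma-voom 1. HAND2 had a log2 fold change of -0.50 (SE 0.18, adjusted p 0.124) and GATA5 of -0.10 (SE 0.17, adjusted p 0.795). Of 23 calcium and conduction genes the gap junction gene GJA1 rose by 2.15 (SE 0.35) and the calcium pump gene atp2a2a stood at -0.67 (SE 0.33, adjusted p 0.265); DESeq2 called 5 of these 23 and limma-voom 1. That list's camera adjusted p was 0.0149, and the adjusted p = 0.557 with an estimated correlation. The camera call was lost without control replicate 1, at 0.0677, and without both libraries numbered 1, at 0.240.

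Energy metabolism lists had medians below 0 with few called genes. None of 90 nuclear genes of oxidative phosphorylation was called by edgeR or limma-voom, against 9 by DESeq2 and 39 with an unadjusted edgeR p under 0.05. Their median was -0.57, and ATP5F1B stood at -0.64 (SE 0.36). None of 13 mitochondrially encoded transcripts was called by edgeR or limma-voom, 1 was by DESeq2, and 0 had an unadjusted edgeR p under 0.05. Their median was -0.49, and MT-CO1 stood at -0.32 (SE 0.45). Of 28 genes of the citric acid cycle OGDH fell by 0.88 (SE 0.19), and of 37 fatty acid oxidation genes the lipase gene LPL rose by 1.49 (SE 0.29). The OGDH call was lost when any 1 library other than mutant replicate 3 was left out, with adjusted p up to 0.0999, and the LPL call without control replicate 3, at 0.0923. Camera adjusted p was 7.34e-18, 0.00241, 5.34e-06 and 0.000391 for these lists, and the adjusted p = 0.557 with an estimated correlation for each. The camera call of the mitochondrially encoded list was lost without control replicate 1, at 0.0546, and without both libraries numbered 1, at 0.0965, and that of fatty acid oxidation without both, at 0.0602. Of 34 glycolysis genes PKLR and HK2 rose by 3.53 (SE 0.30) and 1.39 (SE 0.18), and PFKM and SLC16A3 fell by 2.06 (SE 0.27) and 0.95 (SE 0.24). The SLC16A3 call was lost when any 1 library other than mutant replicate 2 was left out, with adjusted p up to 0.124. DESeq2 called 5 citric acid cycle, 2 fatty acid oxidation and 8 glycolysis genes. The glycolysis camera adjusted p was 0.0536, and it lay under 0.05 without control replicate 3 (0.0393), mutant replicate 2 (0.0272) or mutant replicate 3 (0.0117).

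Cell cycle genes had a median of -0.88, with 1 of 62 called lower and none higher. The count of calls depended on single libraries: 19 were lower without control replicate 1 and 22 without both libraries numbered 1, 2 without mutant replicate 2, and 0 without any other 1 library. DESeq2 called 9 lower, and in none of these settings was a member called higher. The spindle gene PRC1 fell from 45.4 to 11.4 CPM, a call lost when any 1 library other than control replicate 1 was left out, with adjusted p up to 0.157, and PCNA stood at -0.61 (SE 0.31, adjusted p 0.283). The camera adjusted p was 3.55e-10, and the adjusted p = 0.557 with an estimated correlation. None of 82 ribosomal protein genes was called by edgeR, DESeq2 or limma-voom, and 0 had an unadjusted edgeR p under 0.05; their median was -0.07, and 0.21 with library size alone. Their camera adjusted p was 0.586, against 0.000134 without control replicate 1, where the median was -0.29, and 5.97e-05 without control replicate 2, where it was 0.24.

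Stress and handling lists held more rises than falls. Of 30 immediate early genes 10 rose and none fell, 14 higher adjusted over the list alone, with JUNB rising from 20.1 to 92.7 CPM and log2 fold changes of egr1 at 1.82 (SE 0.36), FOSL1 at 3.04 (SE 0.61) and ier2b at 1.43 (SE 0.30). The calls of ier2b were lost without any 1 control, of FOSL1 without control replicates 1 or 2 or mutant replicate 2, and of egr1 without control replicate 2, with adjusted p up to 0.0844, 0.0582 and 0.0534. The count of 10 fell to 3, 1 and 4 without control replicates 1, 2 and 3, and was 6 without mutant replicate 2 or with limma-voom; FOSL1 stood at 3.74 without control replicate 3 and 2.45 without mutant replicate 2. Of 29 hypoxia genes 8 rose and 2 fell, with EGLN3 at 2.57 (SE 0.34), PFKFB3 at 1.88 (SE 0.27) and igfbp1b at 4.97 (SE 0.73), the last from 4.27 without mutant replicate 1 to 5.81 without control replicate 3. Only 3 rose and none fell without control replicate 3, 4 rose and 1 fell without control replicate 2, and 5 rose and none fell without control replicate 1 or mutant replicate 1; none fell without mutant replicate 2 and 1 without mutant replicate 3. Camera adjusted p was 7.12e-07 and 0.0375, and the adjusted p = 0.273 and 0.323 with an estimated correlation. The hypoxia camera call was lost without control replicate 2, control replicate 3 or mutant replicate 3, at 0.0811, 0.0518 and 0.0612. Of 39 heat shock and unfolded protein genes 2 rose and 1 fell, and of 25 p53 and apoptosis genes 2 rose, among them pmaip1 from 3.85 to 17.8 CPM, and 1 fell. Their camera adjusted p was 0.428 and 0.581. With 1 library left out, 0 to 2 heat shock and unfolded protein genes were higher, with none without control replicates 1, 2 or 3 or mutant replicate 3, and 1 to 3 p53 and apoptosis genes. DESeq2 called 6 and 7 genes of these lists.

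Vessel, valve and connective tissue lists were mixed. Of 36 endothelial and endocardial genes 4 rose and 2 fell, with plvapb at 2.36 (SE 0.32). The lymphatic and venous marker lyve1a had 1 count over all control hearts and 145 in mutants, a ratio of 124 (exact 95% counting interval 22.0 to 4950). Its log2 fold change of 6.57 ran from 5.63 to 8.54 with 1 library left out. Of 26 genes of the atrioventricular canal and valves 3 rose, edn1 by 1.97 (SE 0.31), WNT11 by 0.78 (SE 0.20), and WNT9B, which had no count in controls, at least 53.5-fold. The WNT11 call was lost when any 1 library was left out, with adjusted p up to 0.202. Of 40 epicardial and fibroblast genes 7 rose and 1 fell, with BGN at 6.90 (SE 0.79; 6.16 without mutant replicate 1) and loxl2a at 1.44 (SE 0.25). Of 23 smooth muscle and outflow genes 5 rose and 1 fell. The 2 genes carrying the symbol CNN1, a smooth muscle calponin, moved apart. ENSDARG00000017193 rose by 8.77 (SE 0.95), and by 7.97 to 10.74 with 1 library left out. It had 1 control count and a ratio of 579 (exact 95% counting interval 104 to 22889). ENSDARG00000102398 fell by 1.94 (SE 0.21). Of 60 signalling genes 6 rose and none fell, among them ID2 by 1.95 (SE 0.27) and SMAD6 by 1.47 (SE 0.22), both targets of BMP signalling. Of 20 retinoic acid genes 4 rose and 1 fell, with rdh1 at 6.35 (SE 0.69), on 2 control counts with a ratio of 96.2 (exact 95% counting interval 26.3 to 799) and 1.41 of the embryo-labelled count in mutant replicate 1. DESeq2 called 5 valve genes and 13 signalling genes, and limma-voom called 2 retinoic acid genes, 4 signalling genes and 5 fibroblast genes. Camera adjusted p was 0.252, 0.581, 0.00174, 0.324, 0.0313 and 0.364 for these 6 lists, and for the 2 called lists, fibroblast and signalling, the adjusted p = 0.627 and 0.371 with an estimated correlation. The fibroblast call was lost without both libraries numbered 1, at 0.0574, and the signalling call without mutant replicate 3, at 0.166. The endothelial and endocardial list was called lower without mutant replicate 3, at an adjusted p of 0.0240 and a median of -0.28. Of the fibroblast list 4 and 3 were higher without control replicates 1 and 3. Of the smooth muscle list 1 was higher without control replicate 2 or 3, 2 without mutant replicate 1, and 3 without control replicate 1 or mutant replicate 3. Of the signalling list 2 were higher without control replicate 2 or 3, and 3 without control replicate 1, mutant replicate 1 or mutant replicate 2, and of the retinoic acid list 2 were higher without any 1 control or without mutant replicate 1.

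Markers of further tissues gave scattered calls. Of 19 pancreas and intestine genes 4 rose, with apoa4b.1 at 3.94 (SE 0.34) and gcga, with a count of 1.74 of the embryo-labelled count in mutant replicate 1, at 3.22 (SE 0.54; 3.99 without control replicate 2). The list took 0.00260%, 0.0492% and 0.0208% of gene counts in control hearts and 0.0340%, 0.0991% and 0.0123% in mutant hearts, replicates 1 to 3, so the groups overlapped. Of 15 pigment cell genes 6 rose, led by csf1ra at 2.02 (SE 0.22), which macrophages also express. Of 23 adipocyte and lipid transport genes 4 rose, and of 42 fast skeletal muscle genes 1 fell. These lists had camera adjusted p of 0.0110, 0.00405, 0.0149 and 3.99e-05, and the adjusted p = 0.725, 0.323, 0.557 and 0.557 with an estimated correlation. The camera call of pancreas and intestine was lost without control replicate 1, at 0.558, without mutant replicate 2, at 0.181 with a median of -0.49 against 0.55, and without both libraries numbered 1, at 0.621. The adipocyte call was lost without control replicate 1, mutant replicate 1 or both, at 0.0641, 0.164 and 0.194. DESeq2 called 4 skeletal muscle genes, and limma-voom called 3 pigment cell genes and 1 adipocyte gene. Without control replicate 3, 1 pigment cell gene and no adipocyte gene was higher; 3 pigment cell genes were higher without control replicate 2 or mutant replicate 1, and 2 adipocyte genes without control replicate 1. The lists of neural genes (4 higher and 1 lower of 27), cartilage and bone (3 higher and 1 lower of 21), circadian clock (1 higher and 2 lower of 32), skin and gill epithelium (1 higher of 35) and eye (none of 9) had camera adjusted p of 0.489, 0.217, 0.105, 0.666 and 0.449. The higher member of the clock list was lgals2b, a galectin gene, at a log2 fold change of 7.17 (SE 0.99; 8.13 without control replicate 3), and the lower ones were the nuclear receptor genes rorca and rorcb, whose calls were lost when any 1 library other than mutant replicate 2 (rorca) or any 1 other than control replicate 1 and mutant replicate 1 (rorcb) was left out, with adjusted p up to 0.182 and 0.0986. Without control replicate 1, 12 members of the clock list were higher, with a camera adjusted p of 0.000728, and no neural gene was called; without control replicate 3 no neural gene was higher. The skin and gill list had an adjusted p of 0.0307 without control replicate 1, downward, and of 0.00994 without control replicate 2, upward. For the eye list DESeq2 and limma-voom also called 0, and 0 genes had an unadjusted edgeR p under 0.05. Eye list counts summed to 2011 in mutant replicate 1 and 1182 in control replicate 3, against 107 to 258 in the other 4 hearts.

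**Figure D3:**
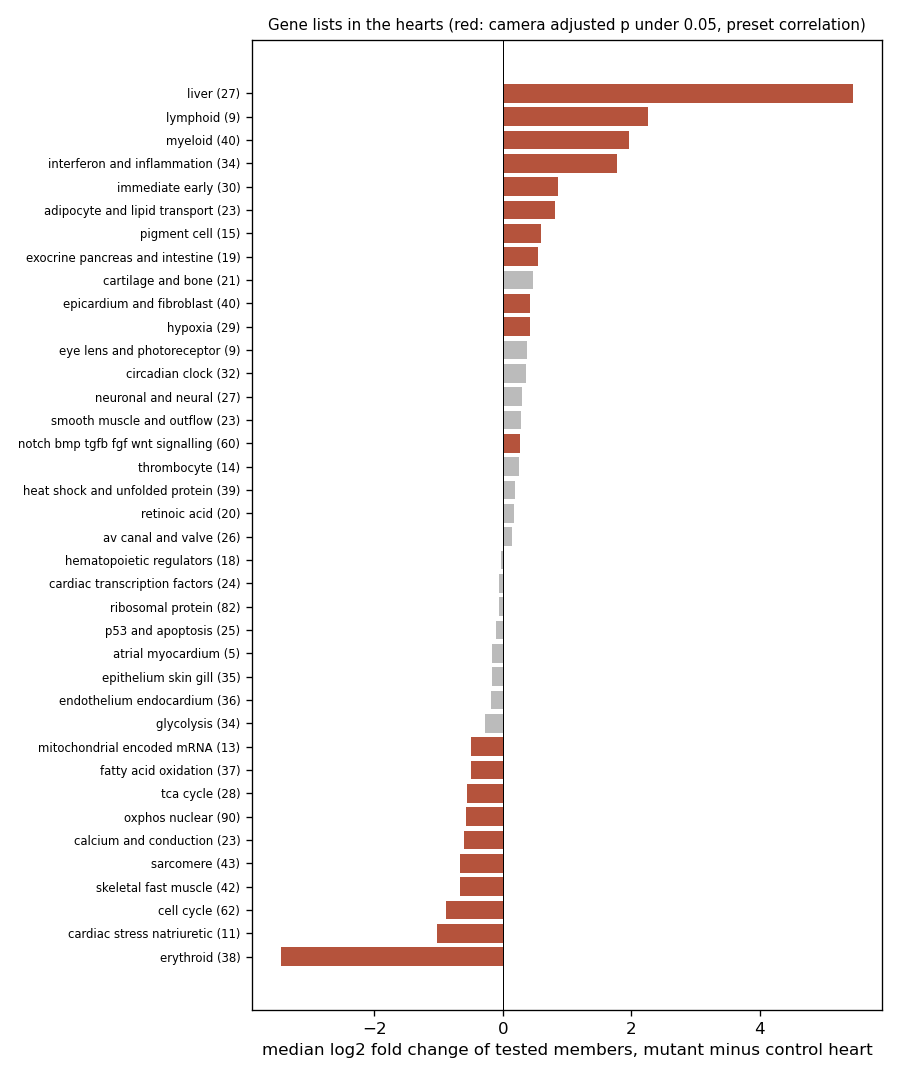
Median log2 fold change of tested members, mutant minus control heart (horizontal axis), for the 38 lists with at least 5 tested members (bars, number of members in brackets). Red bars have a camera adjusted p under 0.05 at the preset correlation, which holds for 21 lists, and for 0 with an estimated correlation; the liver list has the highest median at 5.46 and the erythroid list the lowest at -3.46.

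Between the libraries labelled mutant and control embryo, genes moved opposite to the hearts. This compares 2 files that match heart libraries of the other genotype, and not embryos of the 2 genotypes. Of 12595 genes with at least 100 counts in either library, 3041 passed the 2-fold size rule, 1160 higher and 1881 lower in the library labelled mutant embryo; with library size alone the split was 560 and 2575. The highest were the globin gene HBE1 (ENSDARG00000089087), with 586 counts in the library labelled control and 145800 in that labelled mutant (log2 8.12, exact binomial 95% interval 8.01 to 8.25), and hbaa1 at 8.10 (7.95 to 8.26). Further red cell genes among the 10 highest were alas2 at 5.96, SLC4A1 at 5.70 and cahz at 5.70. The lowest included irg1l, with 5149 counts against 1, and FBP2, PCK1, stm, slc6a14, TAT, UCP1 and lgals2b, at log2 ratios from -10.13 to -9.18, with gja12.1 at 0 counts in the library labelled mutant. The erythroid list had a median of 3.60 and the liver list of -5.12, at percentiles of 100 and 0 among matched random lists, and 29 of 39 lists lay at or beyond the outer 2.5% on either side. Of 1546 genes called in the hearts, 0.129% had the same sign under the embryo labels, against 19.7% of matched random genes. The exact 95% interval was 0.0157% to 0.467%, and it treats genes as independent. The heart calls drew on the 2 matched libraries, so the opposite sign was largely fixed in advance and is no separate evidence. Across 16239 genes, which are not independent replicates, the log2 ratio under the embryo labels had a Pearson r of -0.974 with that between the heart libraries numbered 1.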

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

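The tests in this part were chosen after the result they bear on had been seen, except that leaving out haemoglobin and mitochondrial genes was set before.

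The totals of the embryo-labelled files, outside the replicated heart comparison, were identical to those of heart libraries: 19276348 for the library labelled control embryo and mutant heart replicate 1, and 22649056 for the library labelled mutant embryo and control heart replicate 1. Recounting of the same alignments without strand needs the heart counts to divide the embryo-labelled counts nearly as chance would: the median squared deviation reached 1.03 in the matched pairs, where random division gives 0.455, and lay between 11.5 and 43.9 in the other pairs, which is consistent with such a recount. Separate libraries of similar tissue would deviate as the other pairs do, so the same 1.03 argues against them. Reads from whole embryos of the genotype in the embryo label are argued against by correlations across genes. The lowest r of a matched heart library with the other hearts of its heart label was 0.926. With hearts of the other genotype the highest r was 0.876. MYL7 cannot decide this, since both ends of the heart range of 6102 to 12002 CPM are the matched libraries. It stood at 8180 to 10456 CPM in the other hearts, and at 6311 and 12466 CPM in the embryo-labelled files. The genotype itself was not read from the counts and rests on the labels of the other hearts.

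Red cell transcripts were lower in mutant hearts, with 34 members of the erythroid list called. Globin and mitochondrial transcripts taking many counts could move other genes only slightly. In the heart libraries the erythroid list took at most 5.26% of gene counts, and mitochondrial transcripts 9.17% to 13.3%. Shares of this size argue against that explanation for a median log2 fold change of -3.46. Leaving those genes out could hardly change the calls, so it was a weak test: 24 of 27 erythroid members other than globins were still lower. Less blood of every cell type in the mutant libraries would lower white cell genes too, and 35 myeloid genes rose, but myeloid cells also live in tissue and 3 thrombocyte genes fell, so this may still hold for the red cells. Fewer red cells or less red cell RNA with the mutant genotype, a hypothesis, predicts the same 34 lower members, and the design cannot tell it apart from less blood kept at dissection.

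Liver transcripts were higher in mutant hearts. As the source of the liver transcripts, tissue of other organs in mutant replicate 1 alone is argued against. In both mutant replicates 2 and 3, 26 of 27 liver markers lay above every control library. This does not cover markers of other organs. Eye list counts summed to 2011, 258 and 144 in mutant replicates 1 to 3, and to 1182 in control replicate 3. Liver tissue or liver RNA in the mutant libraries, and liver genes expressed by heart cells of the mutant genotype, both predict what was first seen, a rise of 25 of 27 markers with a median log2 fold change of 5.46. They cannot be told apart by these counts, since either source follows the groups, and no value tested either. Of the 27 markers 2 also stand in another list.

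The 6 heart libraries allow 10 splits into 3 and 3, and 1 of them, the real one, called 1576 genes, while the highest of the others called 0. With 10 splits the share cannot fall under 0.05.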

How the results depend on the processing

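Leaving out both heart libraries numbered 1 and leaving out the 708 genes with an unusual ratio to the embryo-labelled count were chosen after seeing the data; all other alternatives were planned. The heart count of 1576 lay between 1073 (limma-voom) and 2260 (DESeq2) over the settings that kept all libraries, was 1532 without those 708 genes, 1255 without both libraries numbered 1, and ran from 604 to 1302 with 1 library left out, with fewer libraries as the construction. Of the 1576 calls 978 were lost without control replicate 3, and none changed sign under any alternative. The zfpm1 fold change ran from 0.23 to 0.66 with 1 library left out and was never called. The replicate block gave 1476 calls, 1282 of them shared with the 1576; correlations of deviations of the same-numbered hearts were 0.0955, 0.220 and -0.0830, so the numbers were not taken to pair them; with the block 13 of 62 cell cycle genes were lower, against 1, and 22 lists were called, glycolysis added at an adjusted p of 0.0430. Of the 126 called genes that the text draws on, 64 lost the call in some setting, at most 52 in one (without control replicate 3), and none reversed. List calls by camera fell from 21 to 0 with an estimated correlation and to 9 with fry. With the estimated correlation 6 lists had an unadjusted p under 0.05, and the smallest adjusted p was 0.0528. Estimated correlations were 0.79 for nuclear oxidative phosphorylation, 0.71 for cell cycle and 0.22 for liver genes, against the preset 0.01. Preset p-values of such lists assume less correlation than was estimated. Of the 21 lists only hypoxia had an estimate below the preset (0.0046), and its call was lost too. Neither the cause of the fall with fry nor the share due to the correlation was tested. With 1 library left out the camera calls at the preset correlation ran from 19 to 22, with 16 to 20 of the 21 among them. Without both libraries numbered 1 there were 17, of which 15 were among the 21. The 6 lost there were pancreas and intestine, adipocyte, calcium and conduction, mitochondrially encoded, fatty acid oxidation and fibroblast. Under the embryo labels the 3041 genes became 5031 with at least 20 counts and 1399 with at least 500, where 17332 and 5647 genes were admitted against 12595, and 5365 at 1.5-fold and 1647 at 3-fold, among the same number of genes, by the fold minimum itself. In the simulation 14% of 2-fold changes were recovered, so smaller changes can be missed. With 120 simulated calls against 1576 in the hearts, the same adjusted p needed a smaller unadjusted p in the simulation. The 14% therefore need not hold for these data.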

Other observations

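The list of cholesterol synthesis genes and its test were chosen after 4 of its members had been seen to rise, and no test in this part was planned.

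Genes of cholesterol synthesis rose in mutant hearts. Of 23 tested members 17 were called higher and none lower, with a median log2 fold change of 1.41. SQLE rose from 1.49 to 41.6 CPM (log2 4.79, SE 0.31), MSMO1 by 3.93 (SE 0.35) and HMGCS1 by 2.23 (SE 0.18). The regulator gene srebf2 had a log2 fold change of 0.06 (SE 0.20). The hypothesis that the pathway rose as a group was tested on the 18 members other than those seen first: 72.2% were called higher, with a camera p of 0.0133 with an estimated correlation. This is consistent with a rise of the pathway; liver tissue in the mutant libraries, which makes cholesterol, may account for it and was not separated from it.

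EPX, which encodes eosinophil peroxidase, rose from 5.55 ± 2.01 to 415 ± 142 CPM, a log2 fold change of 6.22 (SE 0.40), and was singled out after its value was seen.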
